A study of Homo sapiens with 20 samples.

How the data were processed

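The series holds RNA-seq of 20 xenograft tumors, 5 each of RD control, RD TLE3 knockout, SJRH30 control and SJRH30 TLE3 knockout. Cells of both lines were grafted into NOD/SCID mice, and per the labels the tumors were excised when control tumors reached the size limit, then flash frozen. Poly(A) RNA was selected and made into libraries with a kit that the labels do not state to mark the strand, so genes that overlap on opposite strands cannot be told apart. Groups were taken from the sample titles, and every column of the count table carries the bracketed number of 1 title. No batch, litter, cage, guide or clone is given, and RNA was extracted with 1 of 2 kits without saying which tumor had which.

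Per the submitters' processing notes reads were checked with FastQC, trimmed with fastp 0.20.1, aligned with STAR 2.7 to GRCh38 p7, counted with featureCounts and analysed with edgeR. The notes name these tools without their order or settings and mention no removal of mouse reads. The deposited score values are the authors' normalized counts per gene, scaled between libraries and rounded to whole numbers, so they are not raw counts. Per the file headers the deposited comparison tables hold a linear ratio (FC, fold change) made by the authors for each of 4 comparisons. The log2 fold change in the same tables was deposited by the authors beside that ratio. Each p-value and adjusted p-value in those tables was also computed and deposited by the authors. None of the authors' statistics entered the tests here, and a few of them are printed beside the results.

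The count table lists 57992 genes, of which 13698 have no value in any library and 44294 have values. Gene identifiers were matched to GENCODE 29, where 43815 of those genes were found, and coordinates are GRCh38 from that release. What 1 read is worth in the deposited scale was sought from the spacing of low values. It was taken only where the smallest value above 0 was well above 1. That held in 2 of 20 libraries, with 5 in RD knockout 5 and 11 in SJRH30 control 3. In the 18 others that value was 1 or 2 and no step was taken. In RD knockout 5 a read is worth 4.936 units, with 99.3% of 17795 low values whole steps within 0.1, which gives 9.64 M reads. In SJRH30 control 3 a read is worth 10.895 units (100.0% of 21136 low values), which gives 2.14 M reads. The 18 other libraries hold at least 17.4 M to 40.5 M reads. A gene with 10 normalized counts thus rests on 1 read in SJRH30 control 3, and low genes there are coarse.

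The weight of each library in the authors' mean was found by regression of that mean on the 20 columns over 18857 genes. Weights lay between 0.0588 and 0.0656 in 18 libraries and at 0 in both shallow ones, with a largest error of 0.23%. Leaving out both shallow libraries was therefore added as a second fit after the values were seen, and its counts and list tests are printed beside those of all libraries. Correlation with the other libraries of the group had medians of 0.930 to 0.959 in the deep libraries, 0.860 in RD knockout 5 and 0.731 in SJRH30 control 3. No library was a copy of another, the highest share of identical values being 0.51%. Of 7291 pairs of overlapping genes with a mean above 100, 107 had values within 1% of each other.

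Tests used limma 3.58.1 in R 4.3.3 with a mean-variance trend on log2(value + 1), without rescaling. A gene was tested with a value of at least 1 in at least 5 libraries of the fit, p-values were 2-sided, and a gene was called at Benjamini-Hochberg adjusted p below 0.05. Knockout comparisons used the 10 libraries of their own line. The difference of knockout effects between lines and the comparisons of lines used all 20 libraries with 4 group means. Errors of log2 fold changes are standard errors from the fit, and errors of counts are SD over the libraries of a group. A count model such as edgeR or DESeq2 was not run because the values are scaled and rounded.

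27 gene lists were written before the data were examined. They are TLE family, myogenic regulators, muscle contractile and differentiation genes, Wnt and TCF target genes, Notch pathway, proliferation, cell cycle inhibitors, hypoxia and glycolysis, extracellular matrix, TGF-beta and YAP targets, interferon response, PAX3-FOXO1 target genes and fusion-negative markers. Others are immediate early and heat shock genes, unfolded protein response, cholesterol synthesis, nuclear-encoded mitochondrial genes, ribosomal proteins, mitochondrially encoded transcripts, histones, and markers of endothelial, macrophage, fibroblast and pericyte, adipocyte, erythroid, keratinocyte and neural cells. Each list was tested with camera at a preset correlation of 0.01, adjusted over the lists of a comparison, and again with an estimated correlation. List means per library were compared by exact permutation of the group labels. Overlap between lines used the Fisher exact test on genes tested in both.

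Named genes follow a fixed rule. TLE3 comes first, then other TLE genes, then the 10 largest rises and 10 largest falls among called genes with a mean of at least 5 in the higher group and no overlap between libraries of the groups. Clone, microRNA and small nucleolar names were left out. For the difference between lines the 10 smallest adjusted p were taken. Up to 4 members of a list with the smallest adjusted p and 10 genes chosen beforehand (MYOD1, MYOG, MYF5, MKI67, AXIN2, HES1, PAX3, PAX7, FGFR4, MYCN) were added. Some named genes are left out of the text for space, and genes outside the rule are said to have been chosen after the values were seen.

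The fits were tested on simulated data with 200 changed genes and 1 SD per gene, pooled over the groups of a fit. The noise of a shallow library was thus shared by all libraries of its fit. Changed genes were drawn only from genes above a minimum mean level and outside the lists. In RD 13% of genes changed by log2 1 and 69% of those changed by 2 were called, and 9.89% of calls were false. In SJRH30 these were 0%, 16% and 0%, and without control 3 they were 5%, 58% and 4.55%. For the difference between lines they were 0%, 16% and 5.88%. The alternatives tried were a pseudocount of 0.25, no filter, a stricter filter, median-of-ratios and quantile scaling, library weights, a robust fit, a replicate block, a covariate for host cells, all 20 libraries in 1 fit, a minimum log2 size of 1, and each library left out in turn. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 read the tables and drew the plots.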

Results

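The series measured poly(A) RNA from 20 xenograft tumors of RD and SJRH30 rhabdomyosarcoma cells grown in NOD/SCID mice. Each line was grafted as cells with a non-targeting control guide or with TLE3 knockout, and 5 libraries were made of each of the 4 groups. Of 57992 listed genes, 44294 had values. In 18 libraries the normalized counts summed to between 26.1 M and 60.7 M and 37072 to 42412 genes lay above 0. The other libraries were shallow. RD knockout 5 held 9.64 M reads and 32105 genes above 0, and SJRH30 control 3 held 2.14 M reads and 29206 genes. Mitochondrial transcripts made up 32.4% of RD knockout 5 and 20.4% of SJRH30 control 3, against 2.3% to 16.9% elsewhere. The authors' own mean gives both libraries weight 0, so the counts of each comparison are given for all libraries and for the deep ones, a choice made after the values were seen. The labels do not say that the 5 tumors of a group came from separate mice, so each p-value measures spread between these 5 libraries.

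TLE3, which codes for a Groucho-family corepressor (chromosome 15, 70047790 to 70098176), kept its transcript in every library labelled knockout. Its normalized counts were 1345, 1810, 2622, 1270 and 1809 in the RD controls and 1465, 1357, 1032, 1547 and 424 in RD TLE3 knockout. In SJRH30 they were 426, 638, 185, 597 and 407 in the controls and 967, 806, 582, 637 and 809 in the knockouts. The log2 fold change was -0.69 ± 0.34 (standard error) in RD (limma adjusted p = 0.605) and 0.85 ± 0.37 in SJRH30 (adjusted p = 0.557). In the deep libraries TLE3 changed by -0.36 ± 0.23 in RD (adjusted p = 0.659) and by 0.56 ± 0.28 in SJRH30 (adjusted p = 0.276), and no call was made in either line. Between the control groups TLE3 was lower in SJRH30 (-2.04 ± 0.37, adjusted p = 0.000321). Counts per gene cannot show a frameshift or the loss of a protein, so the knockout is known here from the labels alone.

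Among the other TLE genes, TLE1 had 999.6 ± 227 (SD) counts in RD controls and 2162 ± 732 in RD knockouts, a log2 fold change of 1.05 ± 0.28 (adjusted p = 0.247). Without RD knockout 5 that difference was 1.30 ± 0.21 with adjusted p = 0.0169. In SJRH30 the TLE1 value was 0.53 (adjusted p = 0.837), and 0.07 ± 0.29 without control 3 (adjusted p = 0.919). TLE4 differed by 0.56 ± 0.21 in RD (adjusted p = 0.496) and by 0.91 ± 0.34 in SJRH30 (adjusted p = 0.511). TLE2 (adjusted p = 0.538 in RD and 0.934 in SJRH30) and TLE5 (0.839 and 0.982) did not pass either. Of the 7 tested TLE family genes in RD none passed over all genes (camera adjusted p = 0.356, median log2 0.21, mean -0.05), while 2 were higher and 1 lower when adjusted over the list alone. In SJRH30 none of 6 passed (camera adjusted p = 0.512).

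In RD tumors immediate early genes fell, a group that growth signals and stress switch on within minutes. FOSB, an AP-1 subunit on chromosome 19 (45467995 to 45475179), went from 2551 ± 986 to 45.8 ± 20.5 counts (mean ± SD, 5 libraries per group), a log2 fold change of -5.77 ± 0.35 (limma adjusted p = 3.1e-06). FOS, another AP-1 subunit gene, fell from 4958 ± 4271 to 169 ± 91.2 (-4.60 ± 0.51, adjusted p = 0.00367). The nuclear receptor gene NR4A1 (-3.19 ± 0.39, adjusted p = 0.00428), the zinc finger factor gene KLF4 (-2.98 ± 0.25, adjusted p = 0.000155), the mRNA decay factor gene ZFP36 (-3.24 ± 0.44, adjusted p = 0.00906) and the phosphatase gene DUSP1 (-2.56 ± 0.37, adjusted p = 0.0121) fell too. JUN (-1.90 ± 0.26, adjusted p = 0.0095), JUNB, ATF3, EGR2 and KLF2 fell as well. FOSB, FOS, NR4A1, KLF4 and ZFP36 passed in each of the 10 fits that left out 1 library, and DUSP1 in 9 of them. With a covariate for host cells FOSB (adjusted p = 2.37e-05) and KLF4 (0.014) still passed, while the other 8 called members of the list did not (FOS 0.115, NR4A1 0.229, JUN 0.314, DUSP1 0.454), and 2 genes passed in all. Within the immediate early and heat shock list 10 genes were lower, 0 higher and 15 did not pass, with 14 lower when adjusted over the list alone (median log2 -1.24, camera adjusted p = 2.83e-25). The camera call held with an estimated correlation (adjusted p = 0.042).

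**Figure D1:**
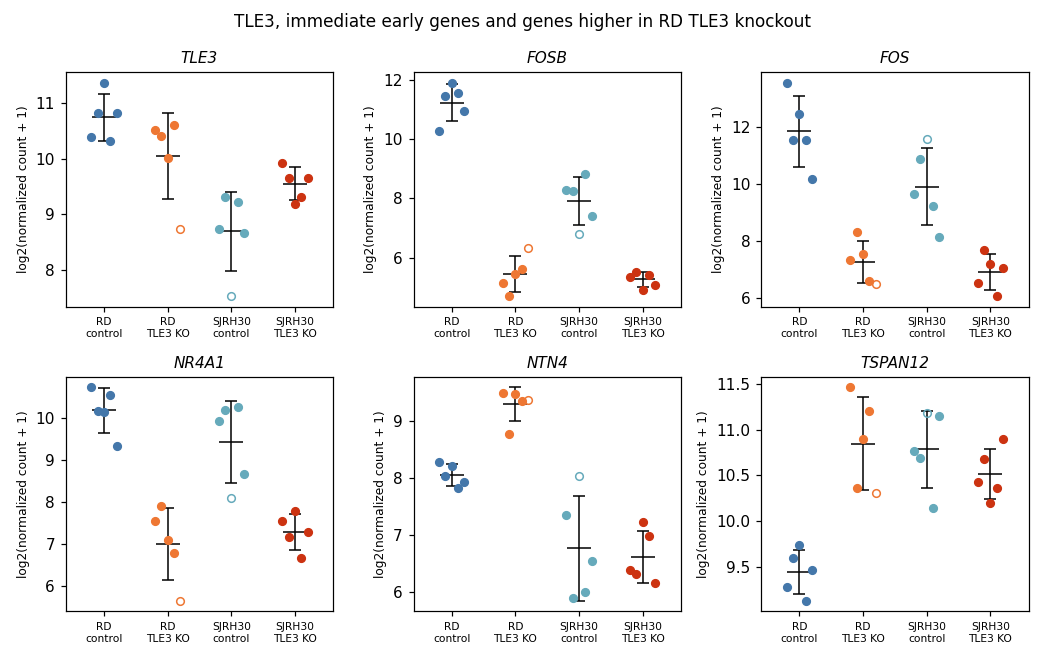
Normalized counts of TLE3, FOSB, FOS, NR4A1, NTN4 and TSPAN12 as log2(count + 1), with points for libraries of the 4 groups, bars the mean ± SD of 5 libraries, open circles the shallow libraries. FOSB goes from 2551 to 45.8 counts in RD while TLE3 overlaps between groups.

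Among other falls in RD, the cytokine gene IL1B went from 101 ± 34.2 to 14.2 ± 2.77 counts (log2 -2.69 ± 0.40, adjusted p = 0.0147), and the chemokine genes CXCL3 (-3.59 ± 0.60, adjusted p = 0.0298) and PF4V1 (-2.81 ± 0.48, adjusted p = 0.0347) fell from low counts. C1QB, a complement gene of macrophages, fell from 1758 ± 680 to 402 ± 156 (-2.11 ± 0.34, adjusted p = 0.0255). The matricellular gene CCN1 (-1.88 ± 0.31, adjusted p = 0.0277) and the interferon factor gene IRF7 (-1.59 ± 0.24, adjusted p = 0.0206) were lower. The metallothionein gene MT1A (-2.79 ± 0.48, adjusted p = 0.0377), the antiviral gene OAS1 (-1.65 ± 0.30, adjusted p = 0.0445) and the stress gene PPP1R15A (-1.80 ± 0.29, adjusted p = 0.0255) also fell. FBXL7, a ubiquitin ligase subunit gene, fell by 1.68 ± 0.21 (adjusted p = 0.00525). Leaving out 1 library at a time, IL1B passed in 7 of 10 fits, C1QB in 5, IRF7 and PPP1R15A in 4, CCN1 and PF4V1 in 3, CXCL3 and MT1A in 2 and OAS1 in 1.

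Fewer genes rose in RD, and by less. NTN4, which codes for a netrin of basement membranes (chromosome 12, 95657807 to 95791152), rose from 267 ± 35.4 to 636 ± 115 counts, a log2 fold change of 1.24 ± 0.22 (adjusted p = 0.0441). TSPAN12, a tetraspanin gene of the Norrin receptor complex, rose from 701 ± 118 to 1938 ± 675 (1.41 ± 0.25, adjusted p = 0.0445). PADI2, which codes for a protein deiminase, rose by 1.53 ± 0.27 (adjusted p = 0.0441), and S100A2, a calcium-binding protein gene, by 1.82 ± 0.32 (adjusted p = 0.0388). CLEC18A (1.61 ± 0.29, adjusted p = 0.0445) and CLEC18C (1.75 ± 0.29, adjusted p = 0.0277) are near-identical lectin genes that may share reads. Their counts differ, with 451 and 316 in RD knockout 1 and 491 and 893 in SJRH30 control 2. TSPAN12 passed in 1 of 10 fits that left out 1 library and the other 5 genes in 2. Without RD knockout 5 the serine protease gene PRSS35 also rose, from 33.6 to 246 counts (2.65 ± 0.40, adjusted p = 0.0126), while the monocyte receptor gene CD14 fell by 3.21 ± 0.43 (adjusted p = 0.0046).

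The macrophage list fell in RD (camera adjusted p = 2.42e-13, median log2 -1.11). In it 1 gene was lower, 0 higher and 17 did not pass, with 12 lower when adjusted over the list alone, and the call was lost with an estimated correlation (adjusted p = 0.125). Its mean per library went from 8.26 ± 0.50 to 7.12 ± 0.30 (SD, 5 libraries, exact permutation p = 0.00794, 0.0265 after adjustment over 10 lists). Without RD knockout 5 the exact permutation p was 0.0159, and 0.0793 after adjustment, at nearly the same change (-1.10 against -1.14), so that call was lost with 1 library fewer. The immediate early list, whose means did not overlap between the groups, had an exact permutation p of 0.00794 there and also 0.0793 after adjustment. The adjusted test is thus too coarse with 1 library fewer, and the lost call does not show a weaker difference. The endothelial list, meant as another marker of host cells, did not differ by the test (7.41 ± 0.52 and 7.35 ± 0.28, exact p = 0.865). How many of its members the tumor cells express themselves was not counted. Interferon response genes were lower too (2 lower, 0 higher, 32 not passing, 13 lower over the list alone, median -0.77, camera adjusted p = 1.62e-10, 0.29 with an estimated correlation). The alignment to the human genome alone leaves open how many of these reads are mouse.

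Other calls in RD came from lists without a single passing gene and were lost with an estimated correlation. PAX3-FOXO1 target genes were higher (27 not passing, 4 higher over the list alone, median 0.18, camera adjusted p = 0.00216, 0.29 with an estimated correlation). Nuclear-encoded mitochondrial genes were lower (35 not passing, median -0.33, camera adjusted p = 0.00216, 0.973 with an estimated correlation), as were hypoxia genes (37 not passing, median -0.36, camera adjusted p = 0.00746, 0.915 with an estimated correlation). Fibroblast and pericyte genes (16 not passing, 1 higher and 6 lower over the list alone, median -0.61, camera adjusted p = 0.0329, 0.973 with an estimated correlation) and extracellular matrix genes (39 not passing, 2 lower over the list alone, median -0.42, camera adjusted p = 0.0411, 0.973 with an estimated correlation) were also lower by camera. Without RD control 4 the adjusted p was 0.193 for the nuclear-encoded mitochondrial, 0.0667 for the hypoxia, 0.0965 for the fibroblast and 0.42 for the matrix list, and without RD knockout 4 it was 0.0747 and 0.0877 for the last pair. Without RD knockout 5 it was 0.426 for the fibroblast and 0.941 (pointing up) for the matrix list, and the matrix call was also lost without RD control 2 (0.0526), RD control 5 (0.266) and RD knockout 2 (0.141). With a covariate for host cells the nuclear-encoded mitochondrial list turned up (0.205), as did the matrix list (5.71e-05), and without RD knockout 5 the cholesterol list passed upward (0.00683, median 0.30, 0.949 with an estimated correlation). Myogenic factors (camera adjusted p = 0.68), muscle contractile genes (0.129), Wnt (0.934), Notch (0.676) and proliferation genes (0.223) did not pass. Cell cycle inhibitors (0.703), TGF-beta and YAP targets (0.184), fusion-negative markers (0.934), the unfolded protein response (0.103), cholesterol synthesis (0.136), ribosomal proteins (0.889) and mitochondrially encoded genes (0.0881) did not pass either, nor did histones (0.479), adipocyte (0.826), erythroid (0.511), keratinocyte (0.157) or neural genes (0.904). The test pointed up against a median below 0 for the myogenic, Wnt, Notch, ribosomal protein and neural lists, and down against a median of 0.02 for the fusion-negative markers.

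None of the genes chosen beforehand for this tumor type passed in RD. The adjusted p was 0.854 for MYOD1 (log2 -0.21), 0.572 for MYOG (0.78 ± 0.35), 0.804 for MYF5 (-0.79), 0.762 for the proliferation marker MKI67 (-0.50), 0.751 for the Wnt target AXIN2 (-0.34), 0.91 for the Notch target HES1 (-0.20), 0.867 for PAX3, 0.794 for PAX7, 0.974 for FGFR4 and 0.985 for MYCN. Over all 42917 tested genes limma called 11 higher and 50 lower, with 3614 at unadjusted p below 0.05 and a median log2 fold change of -0.09. Without RD knockout 5 there were 37 higher and 105 lower, the same 61 genes among them. Leaving out another library gave between 12 and 41 genes, with 0 higher and 12 lower without RD control 2, 3 and 18 without RD control 4, 1 and 20 without RD control 5, 4 and 30 without RD control 1, 4 and 27 without RD knockout 2, 2 and 38 without RD knockout 1, 2 and 32 without RD knockout 3, and 2 and 21 without RD knockout 4. Genes changed in simulated groups with 1 pooled spread per gene were called in 13% of cases at a log2 difference of 1 and in 69% at 2.

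In SJRH30 tumors 4 genes fell over all libraries and 0 rose. KRT18, which codes for a simple-epithelium keratin (chromosome 12, 52948871 to 52952901), fell from 556 ± 361 to 9.2 ± 6.8 counts, a log2 fold change of -5.69 ± 0.75 (limma adjusted p = 0.0422). TMEM273, a membrane protein gene of little known function, fell from 378 ± 41.1 to 48.2 ± 18.3 (-3.03 ± 0.38, adjusted p = 0.0422). The others, named after the values were seen, were the antisense transcript ZNF667-AS1 (-3.73 ± 0.49, adjusted p = 0.0422) and the processed pseudogene AC073055.2 (-5.31 ± 0.60, adjusted p = 0.0302). The kit is not stated to mark the strand and a pseudogene shares reads with its parent gene, so the source of both is uncertain. Without SJRH30 control 3, 3 of the 4 passed and AC073055.2 had too few values to be tested. Over 40028 tested genes 3439 lay at unadjusted p below 0.05, 2558 of them higher, and the median log2 fold change was 0.17.

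SJRH30 control 3 set that count. Without it limma called 78 genes higher and 115 lower among 39720, with the median at 0.03, and leaving out any other library gave 0 genes. Leaving out a further library as well moved these 193 genes to between 36 (without SJRH30 control 4) and 1911 (without SJRH30 knockout 3), with 99, 51 and 449 without SJRH30 controls 1, 2 and 5, and 87, 80, 135 and 49 without SJRH30 knockouts 1, 2, 4 and 5. KRT18 then fell by 6.30 ± 0.53 (adjusted p = 1.84e-05), and it and TMEM273 passed only in that fit of the 10 that left out 1 library. CAPN6, a calpain-like gene of the embryo, fell from 15055 ± 3604 to 1820 ± 1146 (-3.26 ± 0.40, adjusted p = 0.00109). The fibrillin gene FBN3 (-3.27 ± 0.40), the adhesion gene CEACAM21 (-3.47 ± 0.41) and CAPN6 shared that adjusted p of 0.00109. UCA1, a long non-coding RNA, fell by 4.18 ± 0.62 (adjusted p = 0.00446). The stress-response gene CHAC1 (-3.73 ± 0.62, adjusted p = 0.0109), the hyaluronan synthase gene HAS1 (-3.63 ± 0.68, adjusted p = 0.0203), C2CD4C (-3.53 ± 0.60, adjusted p = 0.0122) and the antibody light chain gene IGKC (-3.63 ± 0.66, adjusted p = 0.0164) were lower as well.

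Among rises without SJRH30 control 3, the lipolysis inhibitor gene G0S2 went from 5.25 ± 5.85 to 59.4 ± 34.3 counts (log2 3.42 ± 0.62, adjusted p = 0.016). RGS7, a regulator of G-protein signalling (chromosome 1, 240775515 to 241357230), rose from 261 ± 83.3 to 2398 ± 1925 (2.96 ± 0.41, adjusted p = 0.0029). PECAM1, an endothelial adhesion gene, rose from 160 ± 25.9 to 558 ± 71.9 (1.80 ± 0.28, adjusted p = 0.0064). The granin gene SCG2 (2.48 ± 0.50, adjusted p = 0.0316), the reductase gene MARC1 (2.30 ± 0.36, adjusted p = 0.0064) and the desmosome gene PERP (2.18 ± 0.42, adjusted p = 0.0232) rose as well. The chloride transporter gene SLC26A9 rose by 2.18 ± 0.44 (adjusted p = 0.0316) and the small RNA host gene SNHG23 by 2.18 ± 0.34 (adjusted p = 0.0064). MTRNR2L11 (3.60 ± 0.69, adjusted p = 0.0232) resembles mitochondrial rRNA, so its reads are uncertain. The share of 7SL RNA was 1.69%, 1.14%, 0.5%, 2.14% and 0.96% in SJRH30 knockouts 1 to 5, against 0.3% to 0.64% in the deep controls. RGS7 (2146, 1684, 949, 5754 and 1455 counts) and SNHG23 (10736, 9849, 5769, 20387 and 8675) ranked as that share did. G0S2 (43, 48, 104, 18 and 84) ranked the opposite way. Whether RNA composition underlies any of these rises was not tested.

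**Figure D2:**
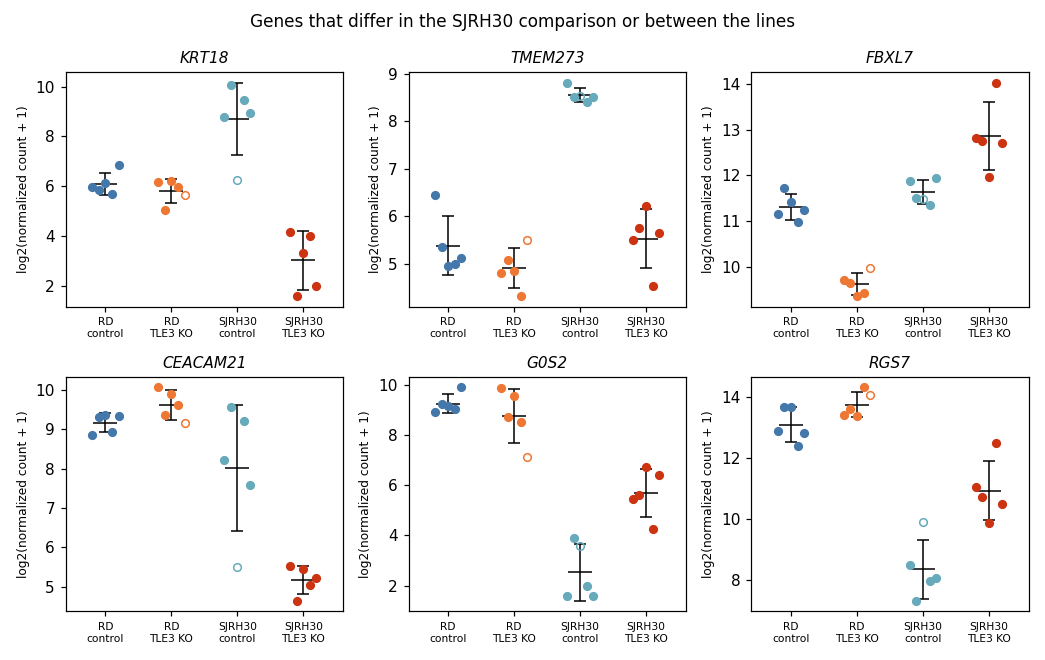
Normalized counts of KRT18, TMEM273, FBXL7, CEACAM21, G0S2 and RGS7 as log2(count + 1), with points for libraries of the 4 groups, bars the mean ± SD of 5 libraries, open circles the shallow libraries. KRT18 goes from 556 to 9.2 counts in SJRH30 and stays near 70 in RD.

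Muscle contractile and differentiation genes were the list with the smallest p in SJRH30 (camera adjusted p = 5.31e-16, median log2 -0.92). The list mean per library did not differ by the exact test, at 9.05 ± 1.21 (SD) in controls and 7.98 ± 0.48 in knockouts. Its exact permutation p was 0.0952, or 0.46 after adjustment, and 0.143 without SJRH30 control 3 (0.458 after adjustment). None of its 66 genes passed over all libraries and the call was lost with an estimated correlation (adjusted p = 0.482). Without SJRH30 control 3, 2 of them were lower, the embryonic light chain gene MYL4 (1620 to 426 counts, -1.95 ± 0.34, adjusted p = 0.0137) and the sarcoplasmic gene SRL (-1.72 ± 0.29, adjusted p = 0.0122). MYMK, which drives myoblast fusion, fell by 1.73 ± 0.36 (adjusted p = 0.0383), and the imprinted RNA H19 fell by 2.24 ± 0.48 (adjusted p = 0.0461). The myogenic regulator list, which holds MYMK, showed no such fall. Its means per library (log2) were 10.04, 10.41, 10.29 and 10.05 in the deep controls and 10.08, 10.07, 10.35, 10.04 and 10.44 in the knockouts. Immediate early genes were lower here too (25 not passing, 5 lower over the list alone, median -0.41, camera adjusted p = 1.32e-05, 0.534 with an estimated correlation). In the deep libraries FOSB fell from 308 ± 117 to 37.8 ± 6.61 (-2.92 ± 0.37, adjusted p = 0.00132), as did FOS (-2.58 ± 0.45, adjusted p = 0.0129), NR4A1 (-2.47 ± 0.36, adjusted p = 0.00364) and EGR1 (-1.86 ± 0.34, adjusted p = 0.0152).

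Erythroid genes (9 not passing, 4 lower over the list alone, median -0.92, camera adjusted p = 1.16e-05, 0.482 with an estimated correlation), extracellular matrix genes (39 not passing, median -0.35, adjusted p = 1.32e-05, 0.741) and fibroblast and pericyte genes (16 not passing, median -0.64, adjusted p = 0.0221, 0.741) were lower in SJRH30 knockouts by camera alone. The fibroblast call was lost without SJRH30 control 1 (0.123), SJRH30 control 2 (0.057), SJRH30 knockout 1 (0.0733) or SJRH30 knockout 4 (0.114). The macrophage (camera adjusted p = 0.141), endothelial (0.52), adipocyte (0.586), keratinocyte (0.944), neural (0.973), Wnt (0.163), Notch (0.52), proliferation (0.944), hypoxia (0.973), interferon (0.52), PAX3-FOXO1 target (0.604) and ribosomal protein (0.336) lists did not pass. Without SJRH30 control 3 more lists were lower by camera, the ribosomal protein (adjusted p = 4.03e-07, median -0.64), unfolded protein response (2.31e-05, median -0.66), nuclear-encoded mitochondrial (3.12e-05, median -0.48), proliferation (0.0134, median -0.35) and macrophage lists (0.0134, median -0.61), and each call was lost with an estimated correlation (adjusted p = 0.679 to 0.729). MYOD1 (log2 0.29, adjusted p = 0.969), MYOG (0.62, adjusted p = 0.902), MKI67 (0.10, adjusted p = 0.976), AXIN2 (-0.11, adjusted p = 0.97), HES1 (0.64, adjusted p = 0.809) and MYCN (0.51, adjusted p = 0.798) did not pass. Simulated genes with a log2 difference of 1 were called in 0% of cases here and at 2 in 16%, so effects of that size, if present, would rarely be called.

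The knockout effect differed between the lines for 4 genes over all 20 libraries. FBXL7 fell in RD from 2560 ± 522 to 792 ± 137 counts and stood at 3207 ± 588 and 8286 ± 4848 in SJRH30, where its rise did not pass (1.22 ± 0.39, adjusted p = 0.455). The difference was 2.91 ± 0.43 log2 (limma adjusted p = 0.0178) and passed in 17 of 20 fits that left out 1 library. KRT18 stayed at 70 and 57.2 counts in RD, a difference of -5.41 ± 0.85 (adjusted p = 0.0224) that passed in 9 of the 20. ZNF667-AS1 (-3.53 ± 0.55, adjusted p = 0.022) and AC073055.2 (-5.77 ± 0.78, adjusted p = 0.00845) followed it. Of 44294 genes 1 was higher and 3 lower, with 2662 at unadjusted p below 0.05 and a median of 0.28. Without SJRH30 control 3 that total was 31, without RD knockout 5 it was 7, without SJRH30 control 1 or SJRH30 knockout 3 it was 6, and without RD control 2, RD control 3, or RD knockout 3 it was 1. It was 2 without RD control 1, RD knockout 1 or SJRH30 control 2.

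In the 18 deep libraries 37 genes were higher and 50 lower in that difference, with the same 4 among them. CEACAM21 (-4.05 ± 0.46, adjusted p = 0.000112) went from 581 to 870 counts in RD and fell in SJRH30. FOSB differed by 3.07 ± 0.47 (adjusted p = 0.00444), with a larger fall in RD, and KLF4 by 2.01 (adjusted p = 0.0355). The FOSB difference lay in the control tumors, with 1234 to 3793 counts in RD and 166 to 453 in the deep SJRH30 controls. The deep knockouts stood at similar levels, 25 to 48 counts in RD and 29 to 45 in SJRH30. MYL4 (-2.97 ± 0.46, adjusted p = 0.00486) went from 450 to 898 in RD. The synaptonemal gene SYCE1 (-3.06 ± 0.47, adjusted p = 0.00444) and the small heat shock gene HSPB2 (-3.04 ± 0.50, adjusted p = 0.00959) differed downward, and HSPB2 overlaps the readthrough HSPB2-C11orf52, so their reads are shared. Immediate early genes formed the list with the smallest p over all libraries (25 not passing, 6 higher over the list alone, median 1.01, camera adjusted p = 3.53e-06), with the call lost with an estimated correlation (adjusted p = 0.87). In the deep libraries it had 2 higher, 0 lower and 23 not passing (adjusted p = 0.00174), while the ribosomal protein list (2.74e-07, median -0.59) had the smallest p, and both calls were lost in the same way (0.798).

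Few calls were shared by both lines. Over all libraries 0 of the 50 genes lower in RD and 3 lower in SJRH30, among 39225 tested in both, coincided. In the deep libraries 4 genes were lower in both, FOSB, FOS, NR4A1 and its antisense neighbour NR4A1AS, where 0.294 were expected (104 and 110 genes of 38896, Fisher exact p = 0.000224). NR4A1AS overlaps NR4A1 and its reads are uncertain. The Fisher test takes genes as independent, so its p-value is too small. The log2 fold changes of all genes correlated at 0.183 over all libraries (Pearson), and at 0.228 in the deep ones. In simulated deep libraries a log2 difference of 2 was called in 81% of cases in RD and 58% in SJRH30, so shared changes can be missed. Averaged over both lines in the deep libraries, FOSB fell by 4.46 ± 0.23 (adjusted p = 1.92e-11) and S100A2 rose by 1.55. That average called 319 genes higher and 267 lower of 44263, and over all libraries 21 and 26. An average can pass through 1 line alone, as with KRT18 (-3.27 ± 0.34), so these are not counts of shared genes.

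In the control tumors PAX3-FOXO1 targets were higher in SJRH30. TFAP2B, a factor that the fusion protein of SJRH30 switches on (chromosome 6, 50818723 to 50847613), had 39.8 counts in RD and 4413 in SJRH30, a log2 fold change of 7.20 ± 0.51 (limma adjusted p = 1.35e-09). The urea-cycle gene ASS1 was higher in SJRH30 by 6.03 ± 0.55 (adjusted p = 5.17e-08), and NELL1, PODXL and the receptor gene FGFR4 (2.66 ± 0.92, adjusted p = 0.046) were higher too. For FGFR4 SJRH30 control 3 had 403 counts against at least 27116 in the other SJRH30 controls, and the deep libraries gave 4.02 ± 0.35 (adjusted p = 2.17e-09). CTAG2, a cancer-testis antigen gene (chromosome X, 154651972 to 154653579), was at 3006 ± 921 in RD and 2.4 ± 4.83 in SJRH30 (-10.58 ± 0.56, adjusted p = 2.11e-11). The envelope gene ERVW-1 rose from 10 to 24122 counts (11.06 ± 0.70, adjusted p = 1.88e-10), and RNF186, MAGEC2, FCRLA and LDOC1 were also higher in SJRH30. XAGE1A, CTAG1B, CSAG1, PNMA5, MAGEA6 and MAGEA3 were lower, though XAGE1A and XAGE1B, CTAG1A and CTAG1B, and MAGEA3 and MAGEA6 are copies with shared reads.

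Of 27 PAX3-FOXO1 targets 21 were higher in SJRH30 controls and 6 did not pass (21 higher and 1 lower over the list alone, median log2 2.58, camera adjusted p = 3.45e-24). That call held with an estimated correlation (adjusted p = 0.00673), and in the deep libraries 23 were higher, 2 lower and 2 did not pass (median 3.04, camera adjusted p = 2.44e-19, 0.00333 with an estimated correlation). The myogenic factor gene MYOD1 was higher by 2.42 ± 0.68 (adjusted p = 0.0143), or 3.37 ± 0.36 in the deep libraries, and MYCN by 2.04 ± 0.35 (adjusted p = 0.000235), while PAX7 (-4.45 ± 0.40, adjusted p = 3.82e-08) and HES1 (-3.70 ± 0.50, adjusted p = 1.03e-05) were lower. PAX3 was higher by 1.25 ± 0.30 (adjusted p = 0.00432). TLE1 was higher by 2.57 ± 0.40 (adjusted p = 6.03e-05) and TLE2 lower (-1.80 ± 0.32, adjusted p = 0.000331). Proliferation genes were higher (14 higher, 0 lower, 26 not passing, 18 higher over the list alone, median 1.08, camera adjusted p = 2.01e-13, 0.578 with an estimated correlation), and extracellular matrix genes lower (0 higher, 16 lower, 23 not passing, 18 lower over the list alone, adjusted p = 0.000912, 0.819 with an estimated correlation). Deep libraries alone gave 33 proliferation genes higher, 0 lower and 7 not passing (median 1.40, camera adjusted p = 8.7e-17, 0.163 with an estimated correlation), and 2 matrix genes higher, 17 lower and 20 not passing (0.00473 and 0.864). The fibroblast and pericyte list also passed by camera over all libraries, but not without SJRH30 control 3 (adjusted p = 0.0706). Its mean was 10.76 ± 0.44 (SD) in RD controls and 9.64 ± 0.67 in SJRH30 controls.

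Over 44294 genes 2758 were higher and 5531 lower in SJRH30 controls, with 14604 at unadjusted p below 0.05, a median log2 of -0.45 and 66.7% of calls lower. Under quantile scaling the median moved by 0.42 and 48.8% of calls were lower, so the split of directions rests on the scaling. Without SJRH30 control 3 the counts were 7128 and 8405, and in the 18 deep libraries 7997 and 9903. Ribosomal proteins (11 higher, 0 lower, 37 not passing, camera adjusted p = 5.76e-10), cholesterol synthesis (9 higher, 1 lower, 16 not passing, 3.94e-06), hypoxia (12 higher, 4 lower, 21 not passing, 1.31e-05) and unfolded protein response genes (3 higher, 0 lower, 17 not passing, 0.00143) were higher by camera. These calls were lost with an estimated correlation (adjusted p = 0.578 to 0.819). Ribosomal proteins in the deep libraries had 43 higher, 0 lower and 5 not passing (median 1.66 against 0.90, camera adjusted p = 6.46e-18), cholesterol synthesis 20, 1 and 5 (6.61e-08), hypoxia 22, 5 and 10 (3.67e-07) and the unfolded protein response 12, 0 and 8 (1e-05), and these calls too were lost with an estimated correlation (0.183 to 0.209). Nuclear-encoded mitochondrial genes went from 1 higher, 1 lower and 33 not passing (0.0066) to 21, 1 and 13 (2.9e-06), lost in the same way (0.819 and 0.347). Myogenic factors (5 higher, 7 lower, camera adjusted p = 0.714), muscle genes (6 higher, 5 lower, 0.721), immediate early genes (5 higher, 10 lower, 0.484), Wnt genes (4 higher, 11 lower, 0.379), Notch genes (1 higher, 6 lower, 0.379) and interferon genes (3 higher, 8 lower, 0.3) did not pass as lists, in the deep libraries either.

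**Figure D3:**
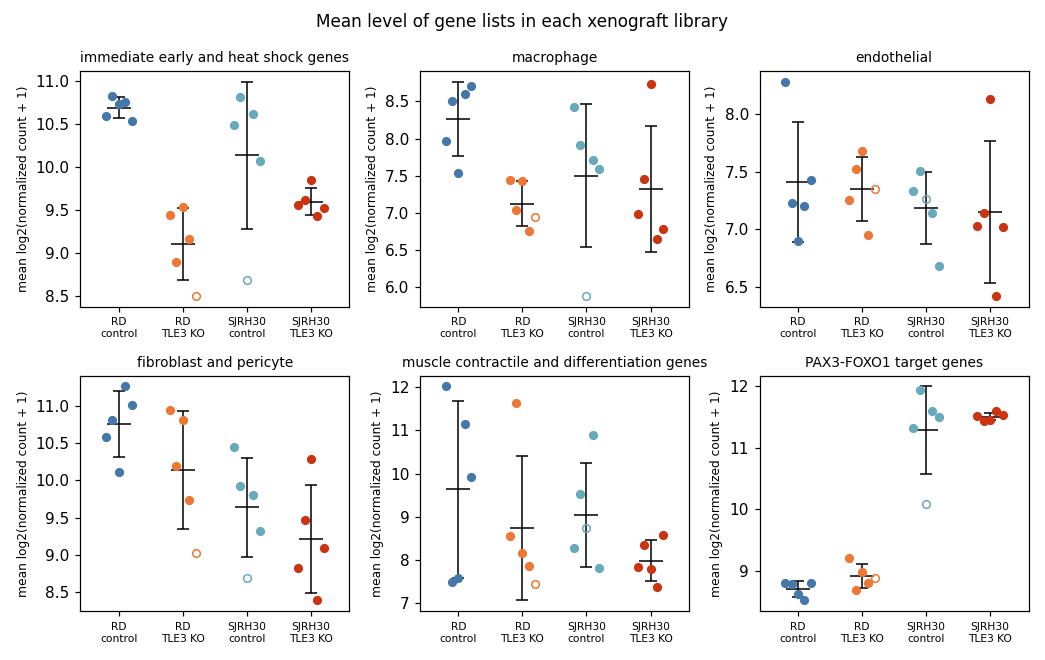
Mean log2(count + 1) per library over 6 gene lists in the 4 groups, with points for libraries, bars for the mean ± SD of 5 libraries and open circles for the shallow libraries. The RD macrophage mean goes from 8.26 to 7.12 while the endothelial mean stays at 7.41 and 7.35.

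Between the knockout groups 3546 genes were higher and 3958 lower in SJRH30, with 13459 at unadjusted p below 0.05, and in the deep libraries 5579 and 6279. PAX3-FOXO1 targets were again higher (22 higher, 1 lower, 4 not passing, camera adjusted p = 6.54e-20), a call that held with an estimated correlation (adjusted p = 0.0167), as in the deep libraries (22 higher, 2 lower, 3 not passing, 3.73e-21, and 0.00215 with an estimated correlation). Proliferation genes were higher as well (20 higher, 0 lower, 20 not passing, camera adjusted p = 7.11e-14), a call lost with an estimated correlation (adjusted p = 0.408), again as in the deep libraries (29 higher, 0 lower, 11 not passing, 3.07e-16, and 0.116 with an estimated correlation). Ribosomal protein, cholesterol synthesis, hypoxia, nuclear-encoded mitochondrial, unfolded protein response and histone lists were higher and matrix, fibroblast and Wnt lists lower by camera in both fits, and none of these calls held with an estimated correlation.

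The authors' deposited tables, from a fit that leaves out the shallow libraries by its mean, list 224 genes with adjusted p below 0.05 in RD (73 higher, 151 lower) and 2990 in SJRH30 (1367 higher, 1623 lower). The authors' log2 fold change for FOSB is -6.106 in RD (adjusted p = 3.14e-45), and for KRT18 in SJRH30 -6.209 (adjusted p = 1.53e-31). For TLE3 the authors give -0.419 in RD (adjusted p = 0.771) and 0.55 in SJRH30 (adjusted p = 0.188). Between lines they list 18615 genes for the controls and 12817 for the knockouts.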

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

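The tests on the immediate early genes, the macrophage genes and SJRH30 knockout 3 were chosen after the results were seen, and so were the fits without the shallow libraries, while the counts over other splits of all libraries were planned.

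In RD the immediate early genes were lower in libraries labelled knockout. The covariate for host cells was 1 mean over the endothelial, macrophage and fibroblast and pericyte lists. The macrophage list fell in RD while the endothelial list did not differ, so this mean cannot exclude fewer macrophages as the cause. With the covariate 10 of the 10 called members kept over 0.5 of their log2 fold change, which argues only against a loss shared by these lists as the whole cause. Their median went from -2.48 (median SE 0.34) to -2.09 (0.40), and 2 still passed with 10 at unadjusted p below 0.05, so most calls ended through a smaller fold and a wider error together. Leaving out 1 outlying library brought the list's median no nearer to 0 than -1.02, which argues against any single library. Handling of the tissue before freezing cannot be told apart from the knockout, because the labels give no times. By limma 0 of 7 heat shock members were lower (median -0.36), which does not exclude it, as immediate early genes answer sooner than heat shock genes. Tumors were excised when control tumors reached the size limit, so in both lines a difference in tumor size would go with the knockout label. Tumor size was not tested. A lower immediate early response in TLE3 knockout tumors may be the biological cause, and these data do not settle it.

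The macrophage genes were also lower in RD knockouts. Fewer host cells of every type are argued against only so far as the endothelial list marks host cells. The macrophage mean minus the endothelial mean per library went from 0.86 ± 0.72 to -0.22 ± 0.26 (SD, exact permutation p = 0.0317, and 0.0476 without RD knockout 5). Against the fibroblast and pericyte mean the change was -0.52 (exact permutation p = 0.0873), and -0.76 without RD knockout 5 (exact permutation p = 0.00794). Leaving out 1 outlying library moved the macrophage median to -0.98 at most. Fewer or less active macrophages in the tumors labelled knockout remain a candidate explanation, and how many list members the tumor cells express themselves was not counted.

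SJRH30 knockout 3 lay with the control libraries at most of the genes called without it. At the 1911 genes called without it and without SJRH30 control 3, its value was nearer to the other knockouts at 27.6% of genes, with a median position of 28.2% of the way from controls to knockouts. Other knockouts left out in the same way lay at 90.3%, 91.2%, 118% and 95.9%, and the controls at 26.1%, -11.4%, 3.96% and 47%. A control tumor under a knockout label is argued against, since at 14 of the 20 genes with the smallest p in a fit without it this library was nearer to the other knockouts, where the controls left out in the same way were so at 0 to 4 and the other knockouts at 20. Sets of 10 to 200 genes kept it above every control (102 of 200 against 8 to 65), while at 500 genes it lay among them (181 against 47 to 248). KRT18 had 9 counts there against 2 to 17 in the other knockouts and at least 445 in the deep controls. More host cells in that library stay open, since its macrophage (8.73), endothelial (8.13) and fibroblast and pericyte (10.29) means were above the other knockouts, and the split of it and the controls from the other 4 called 2792 genes without and 0 with the covariate for host cells (median log2 size 1.48, SE 0.37, against 1.17, SE 0.57). Its 7SL share (0.5%) also lay within that of the deep controls (0.3% to 0.64%), against 0.96% to 2.14% in the other knockouts. A difference in RNA composition thus stays open too and was not tested.

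Other splits of the libraries were counted for each number of called genes, up to 100 per comparison. For each of the 8 numbers 1 to 4 of 100 splits were as large, the real one included, without adjustment over the 8. Chance is unlikely for each number alone but is not excluded, in particular where another split called more genes than the real one. In RD the real split called 61 genes and the highest other 26, with 1 of 100 splits as large. In SJRH30 the real split called 4 and the highest other 0, again 1 of 100. The difference between lines gave 4 genes with a highest other of 107, and 4 splits as large. The control groups gave 8289 with a highest other of 8949, and 3 splits as large, where that split set RD controls 1 to 4 and SJRH30 control 3 against the rest. The knockout groups gave 7504 with a highest other of 936, and 1 split as large. In the deep libraries RD gave 142 (highest other 600, 4 as large), SJRH30 193 (2792, 3 as large) and the difference 87 (164, 2 as large). Splits that call several times the real number point to a structure of the samples besides the groups, as with SJRH30 knockout 3 and, in RD, a split of controls 2 and 3 with knockouts 1, 3 and 4. That RD side had muscle contractile list means of 7.48 to 8.56. The other side, controls 1, 4 and 5 with knockout 2, had means of 9.92 to 12.02. The RD split thus follows muscle transcripts, which are not balanced between the groups, and their effect on the RD calls was not tested.

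In 42 of 248 tested groups of 5 libraries, 1 library stood apart from its group, with a gap to the nearest of the others above 0.71 of the whole range. Chance gives about 1 in 20 such groups, or 5%, and the groups are not independent. RD knockout 5 had the highest total (gap 0.769 of the range), the fewest genes above 0 (0.793), the highest mitochondrial share (0.814) and the highest 7SL share (0.762). SJRH30 control 3 had the highest mitochondrial share (0.907), as did SJRH30 knockout 4 in its group (0.733, 16.9% against 6.2%), and RD control 3 had the highest 7SL share (0.846, 7.38% against 1.4%).

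Among list means, RD knockout 5 (0.736) and SJRH30 control 3 (0.751) were lowest for myogenic regulators. SJRH30 control 3 was also lowest for proliferation (0.824), cell cycle inhibitors (0.796), interferon response (0.748), unfolded protein response (0.712), nuclear-encoded mitochondrial genes (0.803), ribosomal proteins (0.782) and histones (0.722), and highest for mitochondrially encoded transcripts (0.721). RD knockout 2 was highest for muscle genes (0.733, 11.63 against 8.56). RD control 1 was highest for keratinocyte genes (0.898, 9.54 against 4.55) and lowest for ribosomal proteins (0.837). RD control 4 was highest for histones (0.877) and SJRH30 knockout 3 for adipocyte genes (0.871, 6.79 against 5.32).

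Among named genes in RD, 1 library was highest for S100A2 (knockout 4, 0.766), PADI2 (knockout 1, 0.808), CXCL3 (knockout 4, 1.000, at 2 counts against 0), KRT18 (control 5, 0.714), FOXS1 (control 3, 0.740), GCG (knockout 5, 0.846) and SYCE1 (control 3, 0.859). It was lowest for NTN4 (knockout 2, 0.766), DUSP1 (knockout 5, 0.725), HTN3 (control 2, 0.745) and MARC1 (control 3, 0.719). In SJRH30, 1 library was highest for TMEM273 (control 1, 0.722), FBXL7 (knockout 4, 0.747, 16647 counts against 7193), MTRNR2L11 (control 3, 0.907), MAST4-AS1 (control 5, 1.000, at 2 against 0), RGS7 (control 3, 0.749, and knockout 4, 0.751), IGKC (knockout 5, 1.000, at 2 against 0) and HAS1 (knockout 3, 0.857), and lowest for MYL4 (knockout 4, 0.751).

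The knockout effect differed between the lines for KRT18 (adjusted p = 0.0224), ZNF667-AS1 (0.022), FBXL7 (0.0178) and AC073055.2 (0.00845). By camera it also differed for the immediate early (3.53e-06), muscle (0.0147), interferon (0.0147), mitochondrially encoded (0.0143), macrophage (0.0452) and extracellular matrix (0.0452) lists, and each of these list calls was lost with an estimated correlation. The median of all genes in that comparison was 0.28.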

How the results depend on the processing

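Leaving out both shallow libraries, and all alternatives for the comparison of knockout groups and for the overlap of the lines, were chosen after seeing the data, while the others were planned. Outside fits without 1 library, 5675 values of named genes stayed on their side of the threshold, 201 came to pass and 112 no longer passed. Among list calls 1246 stayed, 41 came to pass, 92 no longer passed and 13 changed direction. The cause was not tested unless a reason is given.

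In RD library weights called 125 genes higher and 322 lower, the covariate for host cells 0 and 2, 1 fit of all 20 libraries 1 and 14, and leaving out both shallow libraries 37 and 105. In SJRH30 a pseudocount of 0.25, no filter and the covariate for host cells each called 2 lower, quantile scaling 8 lower, library weights 248 higher and 203 lower, the fit of all 20 libraries 49 and 40, and leaving out both shallow libraries 78 and 115. The difference between lines had 8 genes under quantile scaling, 146 with library weights, 10 with the host covariate, 2 with weights by group and 87 without both shallow libraries. Library weights and leaving out SJRH30 control 3 both lower the share of a noisy library, which fits the larger counts.

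Between controls, library weights called 7358 higher and 9262 lower, the host covariate 4330 higher, and leaving out both shallow libraries 7997 and 9903. Between knockouts, library weights called 7078 and 8644, the 10 knockout libraries alone 5727 higher, and leaving out both shallow libraries 5579 and 6279. Genes shared by both lines numbered 0 over all libraries, 21 with library weights, 3 in the fit of all 20 libraries and 4 without both shallow libraries.

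With the replicate number as a replicate block, RD called 0 higher and 9 lower, SJRH30 0 lower, the difference between lines 0, the control groups 1787 and 3658, and the knockout groups 2401 and 2827, against 3546 and 3958 without it. Correlations between residuals of equal numbers were -0.136 to -0.333 in RD and -0.203 to 0.126 in SJRH30, so the numbers do not pair control and knockout libraries of a line. Between the knockout groups of the lines they were 0.103, 0.235 and 0.275 for numbers 2, 3 and 4, each highest with its own number, and -0.011 and -0.126 for 1 and 5, so a shared factor there stays open.

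In fits without 1 library RD called 0 to 37 higher and 12 to 105 lower, SJRH30 0 to 78 higher and 0 to 115 lower, the difference between lines 1 to 31, the controls 2056 to 7128 higher and 4085 to 8405 lower, and the knockouts 2601 to 3521 and 3027 to 3941. The upper ends for RD came without RD knockout 5, and those for SJRH30, the difference between lines and the controls without SJRH30 control 3.

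In RD, mitochondrially encoded transcripts changed direction with library weights (adjusted p = 0.0291) and with the host covariate (0.0158), which also turned muscle genes (0.0407), extracellular matrix (5.71e-05), fusion-negative markers (0.00671) and nuclear-encoded mitochondrial genes (0.205). Extracellular matrix turned without RD knockout 5 or both shallow libraries (0.941), and fits without 1 library gave it 9.68e-05 to 0.941. In the difference between lines, mitochondrially encoded transcripts turned with library weights (0.514) and without both shallow libraries (0.44), as did proliferation (0.0165) and nuclear-encoded mitochondrial genes (0.0169). Between controls, quantile scaling turned nuclear-encoded mitochondrial genes (0.793) and mitochondrially encoded transcripts (0.565).

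FOSB and KLF4 passed in RD under all 21 alternatives. Quantile scaling moved the median of all genes by 0.11 in RD, -0.16 in SJRH30, -0.26 in the difference between lines and 0.42 between controls. No filter removes no gene in fits of 20 libraries and says nothing there. The values are scaled and rounded and whole reads were worked out in only 2 of 20 libraries, so edgeR and DESeq2 were not run. Depth limits SJRH30 control 3 most, at 2.14 M reads.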

Other observations

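The tests in this part, on neighbouring genes and on TLE1 and TLE4, were chosen after the results were seen.

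Muscle contractile genes varied between tumors of a group more than between groups in RD. Their mean per library (log2) was 12.02, 7.48, 7.59, 11.15 and 9.92 in RD controls and 8.56, 11.63, 8.16, 7.87 and 7.44 in RD knockouts. In SJRH30 it was 8.27, 9.52, 8.73, 10.89 and 7.82 in controls and 7.83, 8.34, 7.78, 7.38 and 8.57 in knockouts. The keratinocyte mean was 9.54 in RD control 1 and between 3.56 and 5.71 in every other library. No test of the source of either was made.

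Genes called in SJRH30 without control 3 lay near each other. Of 191 called genes with a position, 50 had another called gene of the same direction within 1 Mb that did not overlap them. In 1000 random sets of tested genes matched on mean value the median was 20 and the range 4 to 41 (permutation p = 0.000999, the smallest these sets can give). Overlapping genes such as NR4A1AS within NR4A1 and RP11-732A19.5 within DCHS1 were each counted and may share reads. The test takes genes as independent, so its p-value is too small and the size of the excess is uncertain. Chosen after their values were seen, the keratin gene KRT8 (-2.80 ± 0.38, adjusted p = 0.00238), within 1 Mb of NR4A1 on chromosome 12 and overlapping KRT18, protocadherin genes PCDHB2 (-2.11), PCDHB5 (-2.61), PCDHB12 (-2.39) and PCDHB13 (-2.66) on chromosome 5, and zinc finger genes ZNF667 (-2.53), ZIK1 (-2.63), ZNF135 (-2.05) and ZSCAN18 (-2.01) on chromosome 19 were lower. RTL1 (2.13) and small RNAs of its imprinted cluster on chromosome 14 were higher. The SNORD3 genes on chromosome 17 are near-identical copies with shared reads, so they count for less. Neighbouring genes that change together are consistent with a change of chromatin over a region, or with a difference between cell clones, and neither was tested.

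Whether other TLE family members rise where TLE3 was targeted was tested on the pair seen to be higher, TLE1 and TLE4. Averaged over both lines in the deep libraries TLE4 was higher by 0.72 ± 0.18 (adjusted p = 0.0417) with little difference between lines (0.11 ± 0.36, adjusted p = 0.937), but it was picked for being higher in both, so the average restates that and whether the family rises stays open. TLE1 was higher by 0.69 ± 0.16 (adjusted p = 0.0337), but its effect differed between lines at an unadjusted level (-1.23 ± 0.32, adjusted p = 0.135), which argues against a rise in both. The deep averages of TLE2 (0.14 ± 0.19), TLE5 (-0.39 ± 0.23), TLE6 (0.01 ± 0.29) and TLE7 (-0.65 ± 0.51) did not pass, so no rise was found for these. Over all libraries neither TLE1 nor TLE4 passed (adjusted p = 0.301 and 0.192).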
